A study of Homo sapiens with 4 samples.

How the data were processed

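Total RNA of 4 samples of MHCC97H cells was extracted with Trizol and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. The labels put 2 samples in the shNT group and 2 in the shACSL6 group. Nothing in the labels says that the samples of a group came from separate cultures or infections. The p-values of single genes therefore measure only the spread between these samples, which may be technical.

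The authors deposited 1 table per sample with an Ensembl gene identifier and a decimal value that was read here as FPKM, fragments per kilobase of transcript scaled to the library's fragment total. No header names the unit. It was inferred from values that have decimals, that sum to 371407 to 389740 per sample and that share no common step from which whole reads could be recovered. The submitters' processing notes name CASAVA 1.8, Trimmomatic, FastQC, HISAT2, RSEM and edgeR and the build GRCh38, with no roles. The series design text instead describes an alignment with BWA followed by analysis of variance and another with TopHat and Cufflinks, so the aligner and quantifier behind these values are not settled. The annotation release and the use of strand are not given in the sources used here. Every one of the 18837 genes exceeded 0.1 in at least 2 of the 4 samples, tested on the tables, so low genes had been left out before this work. Because the depth is unknown, no counting interval or detection limit is given. FPKM is relative to each library's total, so a group of abundant genes that takes a larger share lowers the value of the others.

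Gene names came from a table of Ensembl identifiers, in which 67 of the 18837 had no name, and positions from GENCODE release 29 on GRCh38. Genes with a mean of at least 1 FPKM over the 4 samples were tested, 12093 in all. Values were taken as log2(FPKM + 1), so log2 differences understate the change of low genes. Groups were compared with limma 3.58.1 in R 4.3.3 (moderated variances with trend and robust settings, group as the only term) and Benjamini-Hochberg adjustment over all tested genes, at a threshold of 0.05. Means and SDs are of FPKM over the 2 samples of a group.

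For counts, the planned test was edgeR's. Since the tables hold no counts, the limma test planned for normalized values was used, and the alternatives planned for counts (DESeq2, its size factors and voom) were not run. The levels of ACSL6, IL18R1 and IL18RAP were not analysed here, so the planned check of the knockdown gave no value.

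Before the data were examined, 30 gene lists were fixed from general knowledge of liver cancer cells, fatty acid activation, IL18 and NF-kB signalling, the cell cycle, stress and other cell types that a culture could hold. The 26 lists with at least 3 tested members were compared with all other genes by limma's camera, with a preset correlation of 0.01 between genes. Adjustment was by Benjamini-Hochberg over the 26. With that preset, camera takes the members of a list as nearly independent, so its p-values do not measure the spread between samples. They can be far too small where members vary together. For each list, genes were also counted that passed over all genes and adjusted over the list alone. Fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes, and camera with a correlation estimated from the residuals were alternatives.

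The rule for named genes was fixed at the same time. It took the title genes with IL18RAP, IL18BP and the other ACSL genes, up to 10 genes per direction past the threshold with a symbol, a mean of at least 5 FPKM and no overlap between groups, and up to 4 members per list with the smallest p. By its second part 1 gene, ATF3, was named.

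Alternatives fixed beforehand were no filter, a mean of at least 5 FPKM, pseudocounts of 0.1 and 5, quantile normalization, median centring, limma without trend, the replicate number as a block, each replicate left out in turn, an adjusted p under 0.01, and at least a 2-fold change. Alternatives chosen after seeing the data included a correction of each sample for a smooth trend (loess, span 0.5) on transcript length and GC content. The others were protein-coding genes without overlaps on the same strand, a crossed block, and each list without genes of the NF-kB target list. Length and GC content were known for 99.6% of tested genes.

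The tests were run on simulated data with the 12093 genes and 2 against 2 samples. Of 100 genes changed 2-fold 80% were called, of 100 changed 1.5-fold 11%, and 1 call was false. The changed genes were taken from well expressed genes only, so these shares do not cover low genes. A list lowered by 0.3 on the log2 scale was found (camera adjusted p = 3.47e-16) and 0 of 29 unchanged lists passed. Noise was drawn independently for each gene and alike for all libraries, and the unchanged lists held random genes. The simulation therefore does not show how often camera falsely calls lists whose members vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.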

Results

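RNA sequencing compared MHCC97H cells, a human hepatocellular carcinoma line of high metastatic potential, after infection with a lentivirus carrying a non-targeting short hairpin (shNT) or a hairpin against ACSL6 (shACSL6). Infection lasted 48 h and was followed by 3 days of puromycin selection. ACSL6 is a long-chain acyl-CoA synthetase, an enzyme that joins coenzyme A to fatty acids. The series title links it to the IL18 receptor chain IL18R1, to NF-kB signalling, to IL18 and to immune evasion of tumours. Each group held 2 libraries, and each library gave a value for 18837 Ensembl genes. The values, read here as FPKM, summed to 380849 and 389740 in the shNT libraries and to 389086 and 371407 in the shACSL6 libraries. No read counts came with them, so the depth of each library is unknown. The genes ACSL6, IL18R1 and IL18RAP were not analysed here. The strength of the knockdown was therefore not checked, and the groups are named as labelled.

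Of the genes the title points to, IL18 could be followed, and it did not pass the test. IL18, an inflammatory cytokine of the IL1 family (ENSG00000150782, GRCh38 chromosome 11, 112143251 to 112164117, minus strand), measured 45.7 ± 2.2 FPKM in shNT and 39.4 ± 0.19 FPKM in shACSL6 (SD, n = 2 each). Its log2 difference on the log2(FPKM + 1) scale was −0.21 with a 95% confidence interval from −0.45 to 0.036, and the adjusted p was 0.964 (limma, Benjamini-Hochberg). The secreted IL18 inhibitor IL18BP measured 2.25 ± 0.032 FPKM in shNT and 2.41 ± 0.42 FPKM in shACSL6. Among the related synthetases, ACSL4 (34.5 ± 2.7 against 37.1 ± 7.9 FPKM), ACSL3 (26.6 ± 1.5 against 27.96 ± 2.0 FPKM) and ACSL1 (2.71 ± 0.19 against 2.55 ± 0.37 FPKM) differed between groups by less than the SD of the shACSL6 libraries and did not pass. ACSL5 measured 1.93 ± 0.13 FPKM in shNT and 1.18 ± 0.061 FPKM in shACSL6, a log2 difference of −0.43, with an adjusted p of 0.833 over all genes and 0.14 adjusted over the list alone (limma, Benjamini-Hochberg). Over the 12 tested genes of acyl-CoA synthesis and fatty acid uptake the median log2 difference was −0.070, and over the 14 tested genes of IL1 and IL18 receptor signalling it was −0.045. Neither list differed from the other genes by limma's camera test (adjusted p = 0.42 and 0.651). The first median turned to 0.013 after a correction for gene length and GC content, and the second to 0.0092 after quantile normalization. With a replicate left out the second ranged from −0.11 (without shACSL6 replicate 2) to −0.010 (without shNT replicate 1).

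ATF3, a stress-induced transcription factor, fell in shACSL6 and was the only protein-coding gene past the threshold that overlaps no other gene on the same strand. ATF3 (ENSG00000162772, GRCh38 chromosome 1, 212565334 to 212620777, plus strand) measured 34.8 ± 2.6 FPKM in shNT and 14.03 ± 0.15 FPKM in shACSL6, a log2 difference of −1.25 (SE 0.107, n = 2 each; limma adjusted p = 0.0331). It was among the 5 of 12093 tested genes past an adjusted p of 0.05, of which 3 were higher and 2 lower in shACSL6. The remaining genes were named after their values were seen. ADORA2A, an adenosine receptor (chromosome 22, 24417879 to 24442360, plus strand), measured 0.961 ± 0.095 FPKM in shNT and 5.76 ± 0.69 FPKM in shACSL6 (log2 difference 1.78, limma adjusted p = 0.0132). The readthrough gene SPECC1L-ADORA2A, which spans the same locus (24270898 to 24442356, plus strand), went from 2.99 ± 0.37 to 0.0352 ± 0.045 FPKM (log2 difference −1.95, limma adjusted p = 0.0132). Because the pair overlaps on the same strand, the split of reads between them is uncertain, and a change in either is not separated from a change in that split. ENSG00000258377, an antisense transcript on chromosome 14 (49620815 to 49623480, minus strand), was listed at 0 in both shNT libraries and at 4.57 and 4.94 FPKM in shACSL6. ENSG00000267904, a sense intronic transcript on chromosome 19 (16639967 to 16640668, minus strand), was listed at 0 in both shNT libraries and at 4.02 and 4.36 FPKM in shACSL6. Both had a limma adjusted p of 0.00384, and both are uncertain. The first lies opposite another gene, from which its reads cannot be told without stated use of strand, and the second overlaps another gene on the same strand.

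At an unadjusted limma p under 0.05, 96 genes were higher and 494 lower in shACSL6. These 590 genes are no more than that threshold gives by chance among 12093 tested genes. The total thus shows no excess of small p-values, and only the direction was uneven. Both shACSL6 libraries lay above both shNT libraries for 1338 genes (11.1%) and below them for 2740 genes (22.7%), where chance gives 16.7% in each direction. Together these shares lie close to the chance total. The share of lower genes at the unadjusted threshold was 83.7% on the deposited scale, 64.8% after centring each library on its median and 61.3% after quantile normalization. All tested genes had a median log2 difference of −0.039, against which the list medians below are to be read. ATF3 lost its call when only genes with a mean of at least 5 FPKM were tested (limma adjusted p = 0.15), without a filter (0.0688), without limma's trend (0.0522) and with protein-coding genes free of overlaps alone (0.0816), while its log2 difference stayed at −1.25.

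NF-kB target genes fell together in shACSL6. Of the 32 tested members of a list of genes that NF-kB is known to induce, 30 were lower and 2 higher, and in 25 both shACSL6 libraries lay below both shNT libraries. The median member fell by 19.5% on the FPKM + 1 scale, a log2 difference of −0.31, and the 4 differences between single shACSL6 and shNT libraries ranged from −0.38 to −0.29. CXCL8, the neutrophil chemokine interleukin 8, fell from 32.9 ± 0.078 to 18.5 ± 0.84 FPKM (log2 difference −0.80, SE 0.101). BIRC3, an inhibitor of apoptosis, fell from 37.3 ± 0.92 to 22.8 ± 1.7 FPKM (log2 difference −0.69). The chemokine CXCL2 fell from 35.8 ± 0.27 to 23.3 ± 0.28 FPKM, and TRAF1, an adaptor of TNF receptors, from 3.29 ± 0.0053 to 1.51 ± 0.048 FPKM. Adjusted over the list alone, 17 of the 32 fell and 0 rose, whereas 0 passed over all genes tested by limma (18 at an unadjusted p under 0.05). Limma's camera test set the list below the other genes (adjusted p = 5.06e-18), with adjusted p = 0.256 with an estimated correlation. The list was drawn up because the series title names NF-kB.

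**Figure D1:**
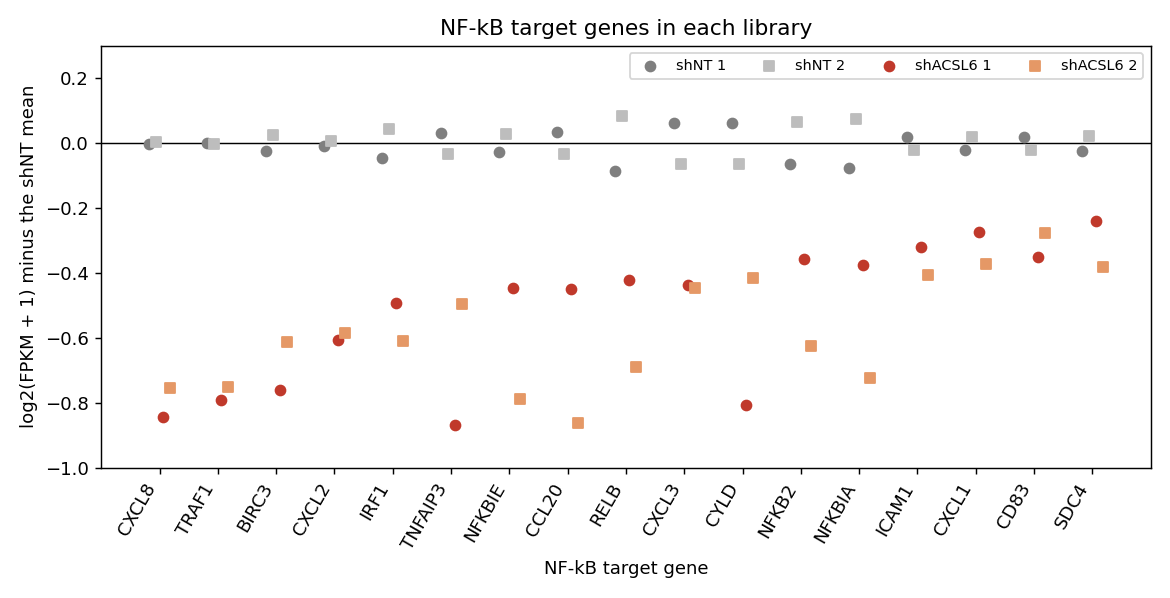
Values of the 17 NF-kB target genes that fell, adjusted over the list alone, in each of the 4 libraries, as log2(FPKM + 1) minus the mean of the shNT libraries. Grey symbols are the shNT libraries and red and orange symbols the shACSL6 libraries. For each gene drawn the shACSL6 libraries lie below both shNT libraries, which largely follows from choosing genes that fell. The other 15 tested members are not drawn.

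Genes of the NF-kB pathway itself also fell as a group. The median log2 difference of the 21 tested components was −0.15, with 18 lower and 3 higher (limma camera adjusted p = 0.00148; adjusted p = 0.345 with an estimated correlation). Adjusted over the list alone, 4 fell and 0 passed over all genes by limma (6 at an unadjusted p under 0.05). RELB, a subunit of the non-canonical NF-kB dimer, fell from 10.8 ± 0.98 to 7.02 ± 1.1 FPKM, and NFKB2, the precursor of its partner p52, from 36.7 ± 2.4 to 25.9 ± 3.6 FPKM. Both also stood in the list of NF-kB targets. Without the 4 members shared with that list the median was −0.091 over 17 genes (camera adjusted p = 0.0263), a comparison added after the data were seen. The remaining genes may still include NF-kB targets that the list does not hold. IKBKE, a kinase related to the IkB kinases, fell from 3.78 ± 0.17 to 2.49 ± 0.29 FPKM, and the adaptor BCL10 from 45.4 ± 2.2 to 34.5 ± 0.79 FPKM. Without shACSL6 replicate 1 the median was −0.093 and the call was lost (camera adjusted p = 0.15).

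Chemokines and cytokines fell as well. Of 19 tested members 16 were lower and 3 higher, with a median log2 difference of −0.29 (limma camera adjusted p = 1.39e-08; adjusted p = 0.256 with an estimated correlation). In this list 8 fell and 0 rose adjusted over the list alone, and 0 passed over all genes by limma (10 at an unadjusted p under 0.05). Beside CXCL8 and CXCL2, the T cell chemokine CCL5 fell from 7.68 ± 0.036 to 4.47 ± 0.90 FPKM and the cytokine IL32 from 28.7 ± 3.6 to 17.5 ± 2.7 FPKM. Members of the NF-kB target list made up 9 of the 19. The other 10 had a median log2 difference of −0.24 (camera adjusted p = 0.00319), a comparison added after the data were seen. CCL5 and IL32 are among these 10. The target list need not hold every NF-kB target, so the comparison does not show a fall of chemokines apart from NF-kB.

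MHC class I antigen presentation genes had a median log2 difference of −0.26, with 15 of 18 lower (limma camera adjusted p = 0.00139; adjusted p = 0.508 with an estimated correlation). HLA-B, a class I heavy chain, fell from 16.1 ± 1.6 to 9.66 ± 1.4 FPKM and was the only member to pass adjusted over the list alone, with 0 over all genes by limma (5 at an unadjusted p under 0.05). Reads shared with other class I genes make the value of HLA-B uncertain. HLA-C measured 26.0 ± 0.53 FPKM in shNT and 19.3 ± 4.9 FPKM in shACSL6, the peptidase ERAP2 7.30 ± 0.10 and 5.58 ± 0.44 FPKM, and the immunoproteasome subunit PSMB10 8.37 ± 1.2 and 4.95 ± 2.1 FPKM. Without shACSL6 replicate 2 the median was −0.13 and the call was lost (camera adjusted p = 0.0701). Immune checkpoint ligands (median −0.12, 16 genes) and interferon-stimulated genes (median −0.091, 24 genes) did not pass (camera adjusted p = 0.19 and 0.234; 0.68 and 0.512 with an estimated correlation), although the latter passed without shNT replicate 2 (median −0.11, camera adjusted p = 0.0425). The median of the checkpoint ligands was −0.061 without shACSL6 replicate 2 (camera adjusted p = 0.929). Among them the galectins LGALS3 (53.8 ± 1.6 against 40.6 ± 8.7 FPKM) and LGALS1 (556 ± 29 against 441 ± 143 FPKM) did not pass either. Of the 33 checkpoint ligands listed, 16 were tested. CD274 (mean 0.212 FPKM over the 4 samples) and PDCD1LG2 (0.126 FPKM) lay below the filter, so the result does not cover them.

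Stress-response genes fell in 3 overlapping groups. Immediate early and heat shock genes had a median log2 difference of −0.23, with 22 of 25 lower (limma camera adjusted p = 1.9e-06; adjusted p = 0.256 with an estimated correlation). Adjusted over the list alone 4 fell, against 1, ATF3, over all genes. Beside ATF3 these were the AP-1 subunit JUN, from 63.0 ± 0.31 to 41.3 ± 5.1 FPKM, the transcription factor KLF6, from 95.8 ± 7.0 to 65.8 ± 0.17 FPKM, and the phosphatase DUSP5, from 38.6 ± 0.48 to 27.9 ± 1.3 FPKM. Without shACSL6 replicate 2 the median was −0.13, still past the threshold (camera adjusted p = 0.001). Targets of p53 had a median of −0.14, with 21 of 24 lower (camera adjusted p = 0.000789; adjusted p = 0.345 with an estimated correlation). Of them 3 fell adjusted over the list alone and 0 over all genes by limma (5 at an unadjusted p under 0.05). GADD45A, a growth arrest and DNA damage gene, fell from 48.6 ± 0.23 to 24.4 ± 2.7 FPKM (log2 difference −0.97, SE 0.115). The cell cycle inhibitor CDKN1A fell from 35.8 ± 0.19 to 23.4 ± 1.6 FPKM and the stress sensor SESN2 from 9.62 ± 0.31 to 6.34 ± 0.59 FPKM. Genes of ATF4 and the unfolded protein response had a median of −0.085, with 25 of 35 lower (camera adjusted p = 0.00959, and 0.622 with an estimated correlation). That is −0.0461 relative to all tested genes, whose own median was −0.039. In that list ATF3, SESN2 and the stress factor DDIT3 (33.8 ± 6.9 to 17.5 ± 4.8 FPKM) fell, adjusted over the list alone. Its call was lost without shACSL6 replicate 2 (median −0.063, camera adjusted p = 0.24), and the median was −0.15 without shNT replicate 1 and −0.16 without shACSL6 replicate 1.

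Hypoxia and glycolysis genes fell in shACSL6, with 30 of 31 lower and a median log2 difference of −0.18 (limma camera adjusted p = 1.39e-08; adjusted p = 0.345 with an estimated correlation). There 5 fell adjusted over the list alone, against 0 over all genes by limma (12 at an unadjusted p under 0.05). NDRG1, a hypoxia-induced gene, fell from 22.1 ± 2.0 to 13.4 ± 0.55 FPKM, the lipoprotein lipase inhibitor ANGPTL4 from 43.5 ± 1.4 to 26.3 ± 4.7 FPKM, the mitophagy receptor BNIP3 from 27.8 ± 1.0 to 18.8 ± 3.0 FPKM and the aldolase ALDOC from 4.21 ± 0.72 to 1.75 ± 0.30 FPKM. ALDOC overlaps another gene on the same strand. Matrix and protease genes had a median of −0.17, with 18 of 22 lower (camera adjusted p = 0.000265; adjusted p = 0.256 with an estimated correlation). Of these, 2 fell adjusted over the list alone and 0 over all genes by limma (4 at an unadjusted p under 0.05). They were the laminin chain LAMB3, from 6.90 ± 0.23 to 3.80 ± 0.51 FPKM, and the interstitial collagenase MMP1, from 351 ± 3.4 to 218 ± 25 FPKM. Epithelial to mesenchymal transition genes had a median of −0.069 over 21 genes and did not pass (camera adjusted p = 0.0809; adjusted p = 0.381 with an estimated correlation). The list lay near the threshold, did not pass without shNT replicate 1 (median −0.098, camera adjusted p = 0.149), without shACSL6 replicate 1 (−0.073, 0.427), with a pseudocount of 0.1 (0.112), after quantile normalization (0.0585) or after median centring (0.0676), and passed as lower without a filter (0.0329), with a mean of at least 5 FPKM (0.0213), with a pseudocount of 5 (0.0419), after the length and GC correction (0.0407), without shNT replicate 2 (median −0.046, 0.0425) and without shACSL6 replicate 2 (median −0.11, 0.0247). There the matrix protein THBS1 measured 10.1 ± 0.31 and 7.24 ± 0.66 FPKM and the transcription factor SNAI2 2.35 ± 0.012 and 1.51 ± 0.0042 FPKM.

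Mitotic genes moved the other way. Of the 40 genes of G2/M and mitosis 37 were higher in shACSL6, and in 29 both shACSL6 libraries lay above both shNT libraries. Their median log2 difference was 0.22, a rise of 16.1% on the FPKM + 1 scale (limma camera adjusted p = 2.31e-17; adjusted p = 0.256 with an estimated correlation). No member passed alone, with 0 adjusted over the list alone by limma and 0 over all genes, though 8 were higher at an unadjusted p under 0.05. PTTG1, the securin that inhibits separase until anaphase, measured 101 ± 2.9 FPKM in shNT and 132 ± 0.39 FPKM in shACSL6. The kinesin KIF20A measured 29.9 ± 1.4 and 37.5 ± 0.80 FPKM, cyclin A2 (CCNA2) 29.03 ± 0.015 and 36.1 ± 2.8 FPKM, and the kinetochore protein CENPF 70.4 ± 0.66 and 89.6 ± 11 FPKM. The median was 0.14 without shACSL6 replicate 2. DNA replication and G1/S genes had a median of 0.026 over 40 genes and did not pass (camera adjusted p = 0.0519; adjusted p = 0.345 with an estimated correlation), with PCNA at 122 ± 2.7 and 135 ± 2.7 FPKM. They passed after median centring (median 0.067, camera adjusted p = 0.0352), with a pseudocount of 5 (0.0342) and after the length and GC correction (0.0344), and the median was 0.0067 without shNT replicate 2 and 0.040 without shNT replicate 1.

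Replication-dependent histone genes, which are near-identical copies whose reads can be split between them, had a median of −0.20, with 9 of 15 lower (limma camera adjusted p = 0.0272; adjusted p = 0.345 with an estimated correlation). Adjusted over the list alone 4 fell and over all genes 0 by limma (6 at an unadjusted p under 0.05), among them H4C8 from 11.6 ± 0.042 to 7.91 ± 0.18 FPKM and H3C2 from 4.41 ± 0.23 to 2.72 ± 0.14 FPKM. The call was lost without shNT replicate 2 (−0.17, camera adjusted p = 0.0615), shACSL6 replicate 1 (−0.19, 0.29) or shACSL6 replicate 2 (−0.22, 0.07), and the median was −0.099 without shNT replicate 1. It was also lost without a filter (−0.054, 0.151), with a mean of at least 5 FPKM (−0.13, 0.609) and with a pseudocount of 5 (−0.087, 0.0712).

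**Figure D2:**
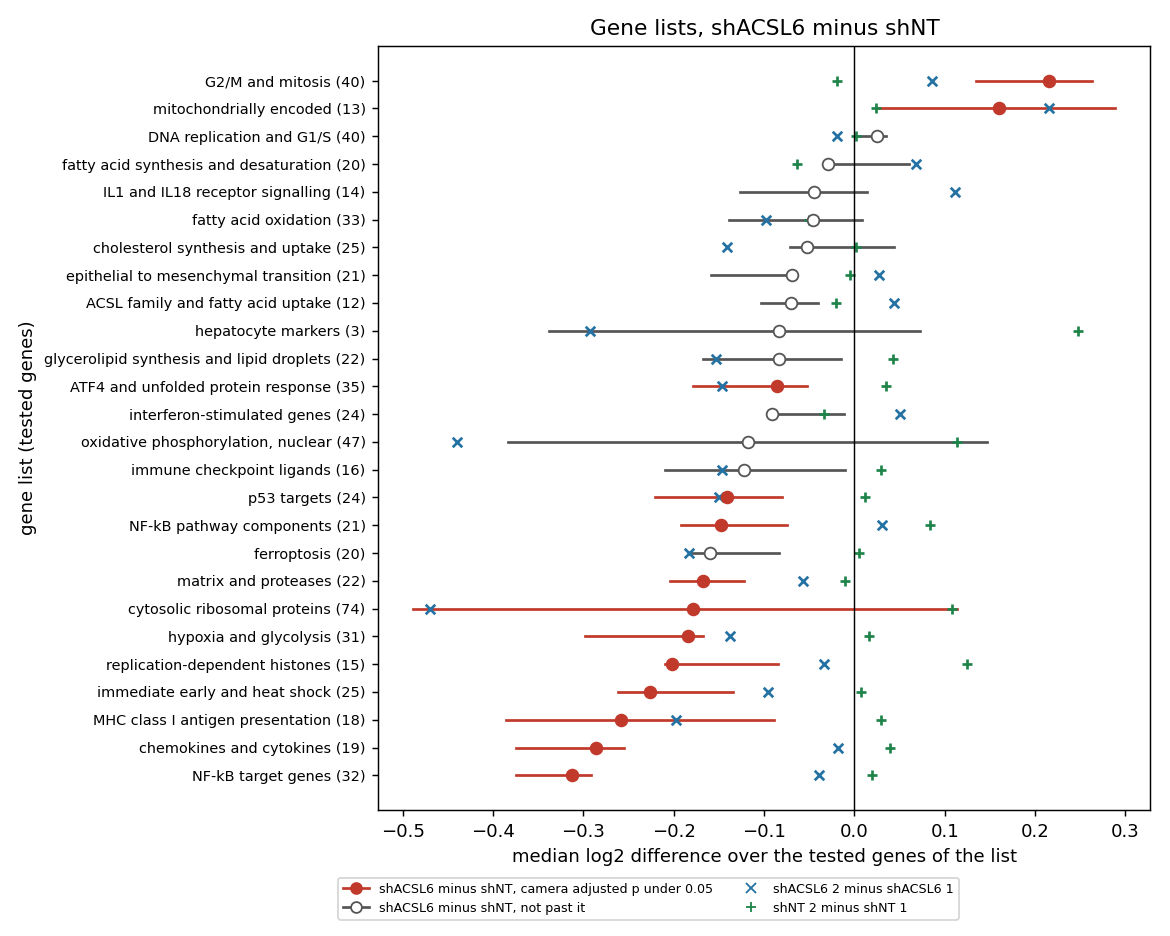
Median log2 difference, on the log2(FPKM + 1) scale, over the tested genes of each of the 26 tested lists. Circles are shACSL6 minus shNT, filled where limma's camera test gave an adjusted p under 0.05, lines span the 4 differences between single libraries, and crosses and plus signs are the differences between the libraries of one group. NF-kB targets lie lowest at −0.31, and the ribosomal protein line spans −0.49 to 0.11.

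The libraries labelled shACSL6 did not resemble each other as closely as the shNT libraries. Their log2 values differed with an SD of 0.286 over genes, against 0.18 between the shNT libraries. By this measure shACSL6 replicate 1 lay closer to shNT replicates 1 and 2 (SD 0.215 and 0.2) than to shACSL6 replicate 2. The libraries thus did not group by hairpin over all tested genes. Component 1 of a principal component analysis (55.9% of the variance) placed shACSL6 replicate 2 at 21.1 and the other libraries between −9.71 and −4.01. The 13 mitochondrially encoded protein genes held 16.4% and 15.9% of all FPKM in the shNT libraries, 16.3% in shACSL6 replicate 1 and 19.8% in shACSL6 replicate 2. Their median log2 difference was 0.16 (limma camera adjusted p = 0.000169; adjusted p = 0.512 with an estimated correlation). It was 0.022 without shACSL6 replicate 2 and 0.28 without shACSL6 replicate 1. Quantile normalization gave a median of 0 (camera adjusted p = 0.562), but it assigns equal values to equal ranks. Abundant genes that keep their rank then show no difference, so that value does not test the change. MT-ND1 measured 4059 ± 68 FPKM in shNT and 4651 ± 532 FPKM in shACSL6. The 74 cytosolic ribosomal protein genes had a median of −0.18 with 67 lower (camera adjusted p = 0.00134; adjusted p = 0.772 with an estimated correlation). That median was −0.44 without shACSL6 replicate 1 and turned to 0.054 without shACSL6 replicate 2 (camera adjusted p = 0.001, higher). RPS20, for example, measured 230 ± 30 FPKM in shNT and 147 ± 56 FPKM in shACSL6. Nuclear genes of oxidative phosphorylation did not pass (median −0.12 over 47 genes, camera adjusted p = 0.234; adjusted p = 0.839 with an estimated correlation). They passed as lower without shACSL6 replicate 1 (median −0.34, camera adjusted p = 2.67e-07) or shNT replicate 1 (−0.17, 0.00567) and as higher without shACSL6 replicate 2 (0.080, 2.61e-05). No gene of these 3 lists passed by limma, with 0 adjusted over the list alone and 0 over all genes, and 1, a ribosomal protein gene, had an unadjusted p under 0.05.

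Lipid metabolism genes did not pass as groups among all tested genes. Fatty acid oxidation had a median log2 difference of −0.046 over 33 genes, fatty acid synthesis and desaturation −0.029 over 20, cholesterol synthesis and uptake −0.053 over 25, and glycerolipid synthesis and lipid droplets −0.084 over 22 (limma camera adjusted p = 0.933, 0.5, 0.648 and 0.186). The camera test, which compares mean test statistics, placed the synthesis list (mean −0.020) and the cholesterol list (mean −0.027) above the other genes, against the sign of their medians. All tested genes had a median of −0.039, which lies above the cholesterol median and below the synthesis median. The first 3 medians turned positive after the length and GC correction (0.0031, 0.020 and 0.0081), and the synthesis list after median centring too (0.012). They also depended on single libraries. The cholesterol median turned to 0.030 without shACSL6 replicate 2, and the synthesis median to 0.020 without shNT replicate 1 and 0.022 without shACSL6 replicate 1. With a replicate left out fatty acid oxidation ranged from −0.086 to −0.00048 and the glycerolipid list from −0.15 to −0.032, without shACSL6 replicate 1 and replicate 2 in turn. Among genes with a mean of at least 5 FPKM the synthesis list passed as higher (median 0.060 over 14 genes, camera adjusted p = 0.0359), against an adjusted p of 0.772 with an estimated correlation over its 20 genes. SCD, the main fatty acid desaturase, measured 133 ± 5.9 FPKM in shNT and 151 ± 10 FPKM in shACSL6, the lipid droplet coat protein PLIN2 62.4 ± 2.1 and 48.7 ± 5.8 FPKM, and the electron transfer flavoprotein ETFA 66.2 ± 4.5 and 55.8 ± 4.2 FPKM. Ferroptosis genes had a median of −0.16 over 20 genes (camera adjusted p = 0.173) and −0.085 without shACSL6 replicate 2 (0.374), with the glutathione-degrading enzyme CHAC1 at 9.90 ± 0.37 and 7.24 ± 1.2 FPKM.

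Hepatocyte markers were measured for 9 of the 40 genes listed, and 3 reached a mean of 1 FPKM. FOXA2, a liver transcription factor, measured 14.4 ± 0.15 FPKM in shNT and 13.6 ± 2.1 FPKM in shACSL6, APOE 7.59 ± 1.0 and 7.45 ± 2.1 FPKM, and ASGR1 1.32 ± 0.31 and 1.07 ± 0.097 FPKM. Their list did not pass (median −0.084, limma camera adjusted p = 0.63), and its median was −0.23 without shACSL6 replicate 1 and 0.063 without shACSL6 replicate 2. The keratins KRT8 (547 ± 19 against 631 ± 8.6 FPKM) and KRT18 (662 ± 35 against 615 ± 35 FPKM) and the mesenchymal filament gene VIM (1271 ± 28 against 1213 ± 82 FPKM) were high in both groups and did not pass. Of the markers of other cell types, 1 fibroblast gene was tested (COL1A1, 26.0 ± 0.41 against 24.4 ± 2.2 FPKM), 1 endothelial gene (KDR, 3.53 ± 0.32 against 3.69 ± 0.31 FPKM), 2 macrophage genes (CD68, 26.7 ± 6.4 against 30.6 ± 2.0 FPKM, and CD14, 2.33 ± 0.18 against 2.31 ± 0.38 FPKM) and 0 lymphocyte genes. None of these 4 genes passed by limma (unadjusted p from 0.257 to 0.919).

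**Figure D3:**
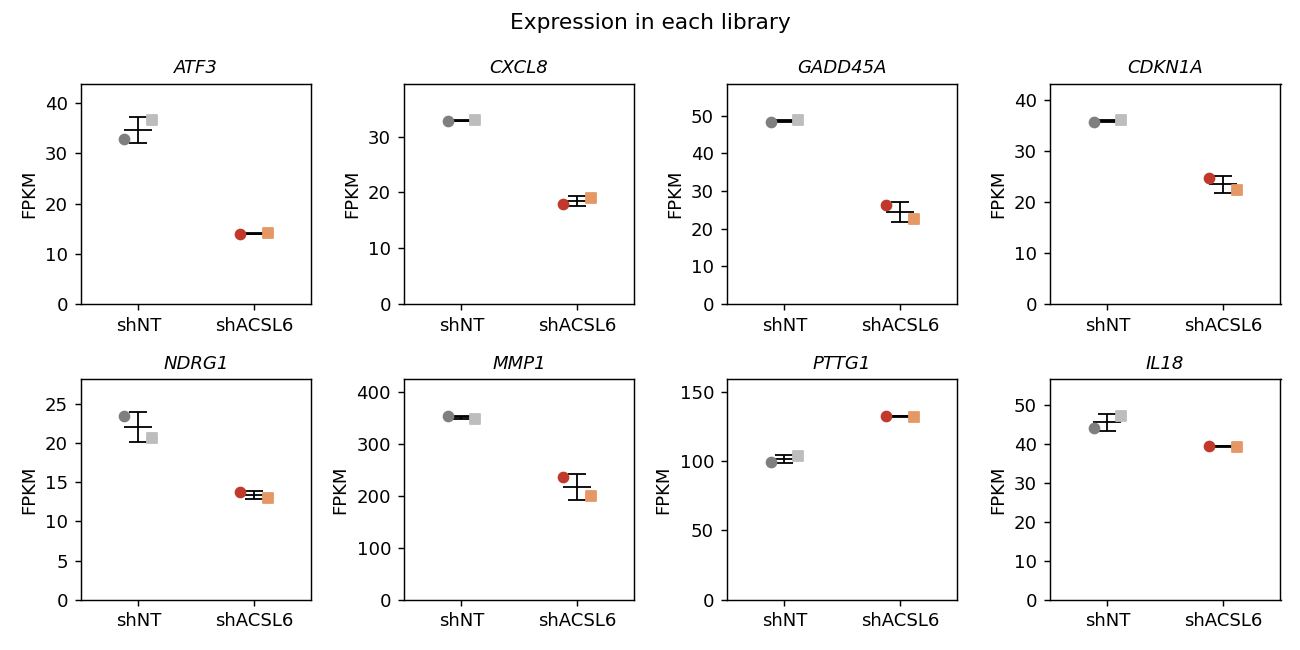
FPKM of 8 genes in each of the 4 libraries, with grey symbols for shNT, red and orange symbols for shACSL6, and black bars for the mean and SD of each group (n = 2). ATF3 goes from a mean of 34.8 to 14.03 FPKM, PTTG1 from 101 to 132 FPKM, and IL18, which did not pass the test, from 45.7 to 39.4 FPKM.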

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

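Settings meant for count data and those for the level of ACSL6 gave no value. The count of genes past the threshold, 5 at first, stayed at 5 with either pseudocount, with quantile normalization, median centring, the length and GC correction and a 2-fold minimum, and was 4 without a filter or without trend, where ATF3 was the gene lost. It was 2 at an adjusted p under 0.01. It was 0 by limma with a mean of at least 5 FPKM (332 at an unadjusted p under 0.05). With protein-coding genes without overlaps it was 0 as well (487 at an unadjusted p under 0.05). Each of these settings removed the 4 called genes other than ATF3 from the test. Leaving out a replicate gave 22 to 1015 genes, each time with all 5 shared: 28 without shNT replicate 1, 22 without shNT replicate 2, 22 without shACSL6 replicate 2 and 1015 without shACSL6 replicate 1. There the lone library was assumed to vary like the other group, and shACSL6 replicate 2, which stands apart, was set against the closer shNT libraries alone. The replicate numbers did not show a pairing: deviations of same-numbered samples correlated at −0.183 over genes, with 2 pairs. With the replicate number as a block 54 genes passed, and with the numbers crossed, a choice made after seeing the data, 25.

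Of the 26 lists, 13 passed camera, 11 lower and 2 higher, and 7 of the 13 kept their direction and call in all 15 other camera fits with the preset correlation: NF-kB targets, chemokines and cytokines, matrix and proteases, G2/M and mitosis, p53 targets, hypoxia and glycolysis, and immediate early and heat shock genes. With an estimated correlation 0 lists passed (NF-kB targets median −0.313, adjusted p = 0.256). That estimate rests on 2 residual degrees of freedom. With fry 4 passed: NF-kB targets, matrix and proteases, histones, and the ACSL family, which had not passed camera (median −0.0697, fry adjusted p = 0.0197). Without shACSL6 replicate 2 the median of cytosolic ribosomal proteins turned to 0.0537 (range −0.443 to 0.0537 over the replicates left out) and that of nuclear oxidative phosphorylation genes to 0.0802 (range −0.337 to 0.0802). The block changed the call of 2 lists, oxidative phosphorylation and epithelial to mesenchymal transition genes, both then past the threshold. Both also passed in several other settings, as did DNA replication genes, while fatty acid synthesis genes passed only among genes with a mean of at least 5 FPKM and interferon-stimulated genes only without shNT replicate 2. The unknown depth limits the low genes most, and values near 1 FPKM carry an error that cannot be given.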

Other observations

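Several further genes near the top of the ranking, named after their values were seen, did not pass over all genes. TXNIP, an inhibitor of thioredoxin that responds to glucose, measured 4.23 ± 0.051 FPKM in shNT and 1.71 ± 0.17 FPKM in shACSL6 (log2 difference −0.95, limma adjusted p = 0.168). The small MAF protein MAFF measured 17.4 ± 0.95 and 9.86 ± 0.56 FPKM, the acute-phase serpin SERPINA3 7.38 ± 0.084 and 4.24 ± 0.073 FPKM, and the growth factor binding protein IGFBP3 10.3 ± 0.36 and 6.20 ± 0.49 FPKM (limma adjusted p from 0.342 to 0.433). The EGF receptor ligand HBEGF measured 4.94 ± 0.024 and 3.07 ± 0.15 FPKM, and the YAP target ANKRD1 20.9 ± 1.0 and 14.2 ± 0.75 FPKM (limma adjusted p = 0.561 for both).

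The tests of culture state, of overlapping gene models, of YAP/TAZ and of NRF2 targets were chosen after the results they bear on had been seen, and the length and GC correction and 3 of the lists were added after seeing the data. For YAP/TAZ targets the median minus that of all genes was −0.0118 over 21 genes, for NRF2 targets −0.134 over 21 genes and for ribosome biogenesis genes 0.0138 over 34 genes. Limma's camera over these 3 lists gave adjusted p = 0.0485, 0.0485 and 0.168, and adjusted p = 0.436, 0.457 and 0.457 with an estimated correlation. After the length and GC correction none of the 3 passed (adjusted p = 0.0922, 0.0922 and 0.122), with 0.0164, −0.111 and 0.033 relative to all genes. Without shACSL6 replicate 2 the values relative to all genes were −0.121 for the YAP/TAZ list, 0.0711 for the ribosome biogenesis list and 0.00331 for the NRF2 list. The leading YAP/TAZ members GADD45A, IGFBP3 and ANKRD1 had been seen near the top of the ranking before that list was tested. Its camera p-values are therefore no independent evidence that these genes fell together. The idea that these groups moved with the knockdown was left undecided.

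NF-kB targets lay below all genes by 0.27 on the log2 scale (list median −0.313). A trend on gene length and GC content is argued against: shACSL6 replicate 2 had a GC trend (Spearman rho −0.401 across genes, which are not independent replicates), the correction brought it to −0.00352, and the list median minus that of all genes stayed at −0.274. A single odd library is argued against too, since without shACSL6 replicate 2 the value was −0.269. Of the 3 ways to split the 4 samples in pairs, 1, the real one, gave a median this far from 0, the highest other being 0.0281, and 1 of 3 gave as many called genes (5, the highest other 2), but 3 splits cannot give a share under 0.05. The state of the cultures at harvest, such as density or handling, may also lower NF-kB targets and stays open, because immediate early and heat shock genes, none of them in the NF-kB target list, fell too (−0.187 relative to all genes, and −0.0999 without shACSL6 replicate 2) and each group may be a single set of dishes. Hypoxia and glycolysis genes fell as well (−0.145 relative to all genes) and G2/M genes rose (0.255), and both may differ with the state of a culture. An effect of the ACSL6 hairpin remains a hypothesis beside that state, and the knockdown was not measured here.

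In the comparison of groups, mitochondrially encoded genes were higher in shACSL6. Ribosomal protein genes were lower by 0.14 relative to all genes on the log2 scale. The length and GC correction left −0.132, which argues against that trend as the whole cause. Without shACSL6 replicate 2 the value was 0.0822. Against shNT replicates 1 and 2 the list median was 0.114 and −0.000653 in shACSL6 replicate 1. In shACSL6 replicate 2 it was −0.371 and −0.488. The fall was therefore seen in shACSL6 replicate 2 and not in shACSL6 replicate 1. What set shACSL6 replicate 2 apart, its RNA, its preparation or its culture, was not tested.

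Overlapping gene models made up 32% of the 50 genes with the smallest p (16 genes) and 15.6% of all 12050 placed genes (1877). These genes had been seen at the top of the ranking before they were counted, so the share tests nothing. Beside the pair of SPECC1L-ADORA2A and ADORA2A, FAM47E-STBD1 measured 2.46 ± 0.23 and 0.158 ± 0.22 FPKM and STBD1 1.38 ± 0.15 and 3.00 ± 0.19 FPKM (limma adjusted p = 0.115 and 0.387). The other 3 readthrough models among the 50 were ABHD14A-ACY1 (log2 difference −1.41), RNASEK-C17orf49 (−1.21) and RPS10-NUDT3 (0.66). None of them passed over all genes (limma adjusted p = 0.387, 0.387 and 0.491), and neither did their partners. At these loci the upstream genes differed by −0.034, −0.13 and −0.36 and the downstream genes by 0.059, 0.26 and 0.047. The assignment of shared reads to one model or the other and a switch between transcripts in the cells both stay open for these loci, since without reads over the junctions they were not separated.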
